A study of Homo sapiens with 12 samples.

How the data were processed

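Polyadenylated RNA from 12 cultures of EndoC-βH1 cells was sequenced on an Illumina HiSeq instrument, with random hexamer priming and no strand marking stated in the labels. Without strand information, reads from transcripts on opposite strands of a locus cannot be separated, and this holds for TUNAR as for other genes. The cells had received negative or TUNAR siRNAs with a lipid reagent and, 2 days later, 1-AKP at 5 µM or DMSO at 1:1000 for 24 hours. There are 3 libraries in each of the 4 groups, replicates 1 and 2 at passage 74 and replicate 3 at passage 75.

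The deposited files give, for each library and gene, an expected count, per the file headers: an estimated read count that is not normalised. The authors also deposited FPKM for the same genes, which are fragment counts scaled by gene length and by library total. The deposited length column, which belongs to no standard expression unit, gives a gene length in bases. The submitters' processing notes name RSEM, Bowtie and BWA and the builds GRCh37 and hg19, without versions or roles. Genes were keyed by Entrez Gene ID and only genes above 0 were listed, between 18787 and 18994 per library and 16899 in all 12. A gene that was not listed in a library was taken as 0. Between 35.3% and 36.0% of expected counts were not whole numbers, and they were rounded before the fits. The totals ran from 15653786 to 15986834 expected counts per library, and the 10 most abundant genes took between 7.20% and 7.97% of them. Of 21508 identifiers 21386 were matched to current gene symbols and 122 were not, which kept their identifier. Of the symbols in the gene lists, 589 of 613 entries were matched. Pairs of libraries were checked for duplicates by the chi-square per degree of freedom of their counts, which ran from 2.37 to 11.9 within groups, so no library was a copy of another of its group; pairs between groups were not compared.

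Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15990 genes holding 99.9% of the counts. Libraries were scaled by TMM, with factors from 0.990 to 1.014. One negative binomial fit of the 12 libraries with 4 group means was made in edgeR 4.0.16 under R 4.3.3 (glmQLFit with robust estimation), with 8 residual degrees of freedom and a common biological coefficient of variation of 8.74%. Each comparison was a contrast in this fit, tested with edgeR's quasi-likelihood test and the Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. The contrasts were TUNAR against negative siRNA in DMSO and in 1-AKP, 1-AKP against DMSO with negative and with TUNAR siRNAs, and the difference of the siRNA effects between treatments. TUNAR was also compared by exact two-sided permutation tests, which cannot go below p = 0.1 with 3 libraries against 3.

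The replicate numbers were checked for pairing by correlating, over genes, the deviations of libraries from their group means. In the siRNA comparisons the libraries with the same number correlated at 0.376, 0.178 and 0.217 in DMSO and at 0.416, 0.162 and 0.286 in 1-AKP. All were over 0.1, the minimum fixed for treating the numbers as pairs, so the fit with replicate number as a block (6 residual degrees of freedom, coefficient of variation 2.86%) is given beside these comparisons. The labels do not say what a number marks beyond the passage. In the 1-AKP comparisons 1 of the 3 correlations lay below 0.1, and the block fit is given only among the alternatives. The block fit takes the same shift of a replicate number in all 4 groups. Its 6 residual degrees of freedom therefore also rest on pairing across treatments, which did not meet the rule.

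The 30 gene lists covered Wnt and GSK3 signalling, the cell cycle, beta-cell identity and secretion, metabolism, stress responses, markers of other cell types, and genes near the TUNAR locus. They were fixed before the data were examined and each is reported with its result. Of the 18 entries of the replication-dependent histone list 8 were tested, in polyadenylated RNA only, so total histone RNA was not measured. Lists were tested on log2 CPM (prior count 2) with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Counts of called members are given over all genes tested and adjusted over the list alone. The named genes follow a rule: TUNAR and 13 focus genes; the 10 risen and 10 fallen genes with the largest fold among called genes with a mean log2 CPM of at least 1 and no overlap between groups (5 and 5 in the comparisons within the other treatment or siRNA); and up to 4 called members of each list with the lowest p. The rule was applied to the block fits of the siRNA comparisons as well, a step added after the data were seen. Loci without a descriptive name were counted and not named. CCND1 and HHEX did not pass the filter, and 1 other focus gene was not analysed here.

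Alternatives were the replicate block, passage as a covariate, passage 74 alone, DESeq2 size factors, library size only, no filter, a filter of 50 counts in 3 libraries, the Wald test of DESeq2 1.42.0, limma on log2 FPKM with a pseudocount of 1 (FPKM of at least 1 in 3 libraries), with a pseudocount of 0.1 and without the filter, the 6 libraries compared alone, and leaving out each library. Added after seeing the data were a fit without the replicate 1 libraries, a fit with each library's trend over gene length removed (lowess, span 0.3), and the same alternatives of the block fits. For 3′UTR sequences, reference transcripts of GENCODE were searched for all 16384 sequences of 7 bases, and the log2 fold changes of the block fit were regressed on the presence of each that occurs in at least 100 genes, with 4 covariates. Lists matched on length and mean expression were drawn 10000 times from the 50 nearest genes of each member. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

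The tests were tried on simulated data with the depth of these libraries and the replicate shifts and spread of the block fit, which favours that fit. The data held 15990 genes, of which 67, 67 and 66 were changed by 1.25, 1.5 and 2 fold. For TUNAR siRNAs in DMSO, the fit without pairing found 22.4%, 67.2% and 77.3% of them and the block fit 71.6%, 92.5% and 95.5%. For 1-AKP with negative siRNA these were 20.9%, 71.6% and 86.4%, and 67.2%, 88.1% and 97.0% with the block. Unchanged genes made up 1 of 112 and 0 of 119 calls without the block, and 16 of 189 and 20 of 188 with it. Both shares with the block lay above the threshold on adjusted p. A list of 30 raised genes had a camera p of 5.82e-116 and a list of 30 unchanged genes a p of 0.644. In the same tests a 7-base sequence with an added shift ranked first, and without a shift the lowest statistic was -4.08.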

Results

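Polyadenylated RNA was sequenced from EndoC-βH1, an established human beta-cell line of fetal pancreatic origin that makes insulin. Cells received either a negative control siRNA or siRNAs against TUNAR, a long noncoding RNA, and were afterwards treated with the GSK3 inhibitor 1-AKP at 5 µM or with its solvent DMSO for 24 hours. The 12 libraries form 4 groups of 3: negative siRNA with DMSO, TUNAR siRNAs with DMSO, negative siRNA with 1-AKP, and TUNAR siRNAs with 1-AKP. Replicates 1 and 2 of each group came from passage 74 and replicate 3 from passage 75. Each library held between 15653786 and 15986834 expected counts, and 15990 genes passed the filter on low counts. Levels are given as CPM, normalised counts scaled to a fixed library total, with the mean ± SD of 3 libraries, and changes as log2 fold changes from edgeR's quasi-likelihood test with its standard error (SE) and a Benjamini-Hochberg adjusted p. The comparisons, the gene lists and the rule for naming genes were fixed before the data were examined. Applying that rule to the siRNA fits with replicate number as a block was added after the data were seen. The p-values measure only the spread between these samples, which come from one cell line.

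The clearest differences between libraries followed both the replicate number and 1-AKP. The first principal component held 23.7% of the variance and the second 18.9%. Replicate 1 had the lowest first-component score of its group in all 4 groups, at -26.4 and -25.7 in DMSO and -10.7 and -10.2 in 1-AKP. Within each replicate number and siRNA, the 1-AKP library had the higher score on the second component. Replicate 1 libraries also held more RNA of mitotic genes: the median log2 difference of the 28 tested G2/M genes from replicates 2 and 3 was 0.57, and CCNB1, the mitotic cyclin B1, averaged 161 CPM against 96.9 and 105. SST, the somatostatin hormone gene, averaged 29.7 CPM in replicate 1 against 4.05 and 5.49, and G6PC2, the islet glucose-6-phosphatase subunit, 21.8 CPM against 87.8 and 126. The median difference of the 9 markers of other islet cells was 0.23, that of the beta-cell transcription factors was -0.16, that of the insulin secretion genes -0.11, that of the glycolysis genes -0.10 and that of the S-phase genes -0.12. Lists of other kinds differed too: secreted Wnt antagonists by 0.42 (3 tested), fibroblast and stellate markers by 0.34 (4), duct and acinar markers by -0.30 (6) and immediate early genes by 0.21 (18). Each group holds 1 such library.

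**Figure D1:**
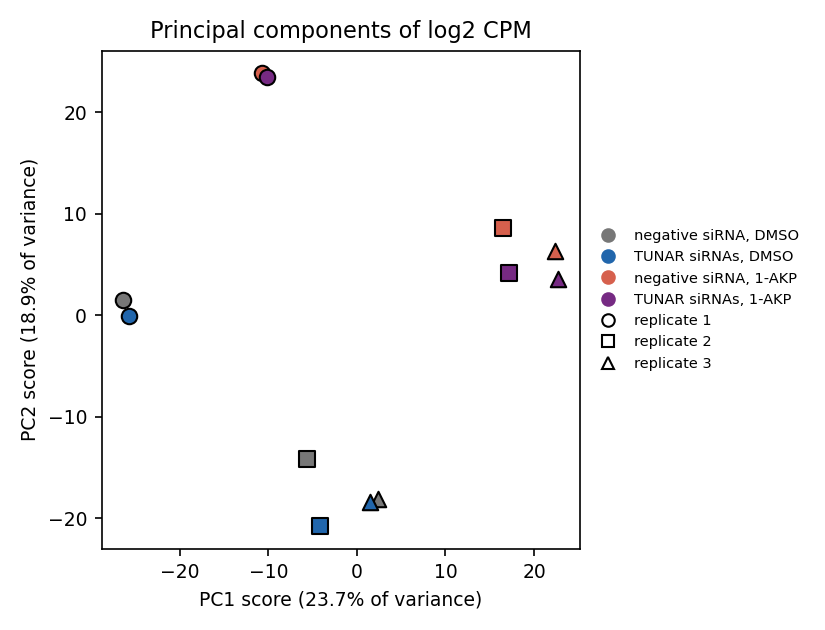
Scores of the 12 libraries on the first principal component (horizontal axis, 23.7% of variance) and the second (vertical axis, 18.9%), with colour for the group and the marker for the replicate number. Replicate 1 of each group lies to the left of its group, at scores from -26.4 to -10.2.

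TUNAR (Entrez Gene 100507043) was the target of the siRNAs. Its level with negative siRNA and DMSO was 14.4, 19.9 and 17.7 CPM in replicates 1, 2 and 3 (17.3 ± 2.76, SD, n = 3). With TUNAR siRNAs and DMSO it was 3.83, 7.2 and 8.09 CPM (6.37 ± 2.24), which is 36.8% of the level with negative siRNA. In 1-AKP, TUNAR stood at 27.9, 31.0 and 30.8 CPM with negative siRNA (29.9 ± 1.69) and at 6.95, 10.5 and 13.6 CPM with TUNAR siRNAs (10.3 ± 3.32), or 34.5% of it. Every library with TUNAR siRNAs lay below every library with negative siRNA of the same treatment. Cells given 1-AKP held 172% of the DMSO level with negative siRNA and 162% with TUNAR siRNAs. In the test without pairing, the log2 fold change of TUNAR with its siRNAs was -1.44 in DMSO (SE 0.263, adjusted p = 0.248) and -1.53 in 1-AKP (SE 0.245, adjusted p = 0.159). With the replicate number as a block, these were -1.45 (adjusted p = 0.00248) and -1.55 (adjusted p = 0.000674). The exact two-sided permutation test gave p = 0.1 for both, the smallest that 3 libraries against 3 allow. The block calls ended when replicate 2 was left out, at adjusted p = 0.156 in DMSO and 0.0876 in 1-AKP, and without replicate 1 of the group with TUNAR siRNAs and DMSO the unpaired adjusted p in 1-AKP became 0.0371. TUNAR changed by 0.79 with 1-AKP and negative siRNA (SE 0.234, adjusted p = 0.0718) and by 0.70 with 1-AKP and TUNAR siRNAs (SE 0.274, adjusted p = 0.164), neither past the threshold, with exact permutation p = 0.1 and 0.3.

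**Figure D2:**
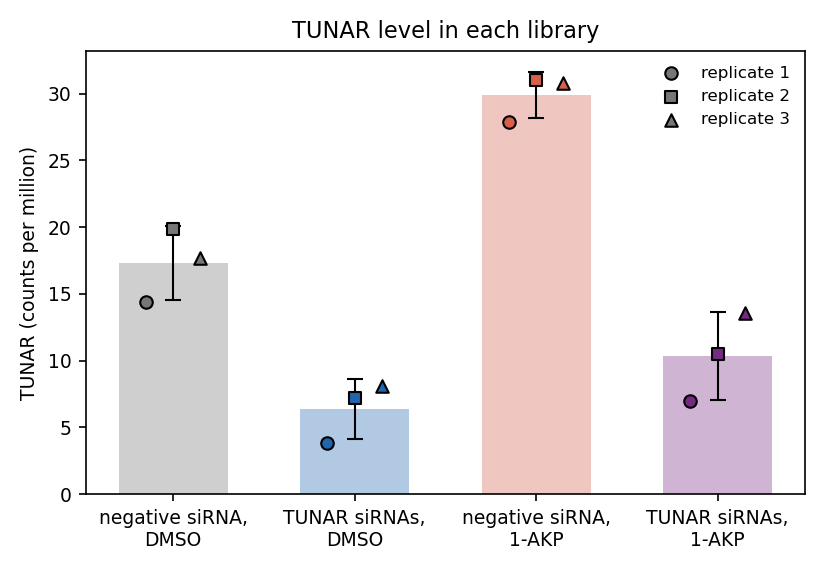
TUNAR level in CPM (vertical axis) in the 4 groups (horizontal axis); points are the 3 libraries of a group, and the bars with error bars are the mean and SD. The means are 17.3 and 6.37 CPM in DMSO and 29.9 and 10.3 CPM in 1-AKP, for negative and TUNAR siRNAs in that order.

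TUNAR siRNAs in DMSO were compared with negative siRNA in DMSO to ask which genes depend on TUNAR in untreated cells. SYPL1, a vesicle membrane protein related to synaptophysin, fell from 106 ± 4.72 to 70.7 ± 7.05 CPM (log2 fold change -0.58, SE 0.076, adjusted p = 0.0342). B4GALT4, a Golgi galactosyltransferase, fell from 81.6 ± 3.64 to 56.2 ± 4.27 CPM (-0.54, SE 0.065, adjusted p = 0.0289). The annotated 3′UTRs of both genes hold 7-base sequences that were among those most associated with lower levels after TUNAR siRNAs in these libraries. Both genes were part of that search, and 25.2% of all genes with an annotated 3′UTR hold at least 1 of these sequences. These were the only genes past the threshold without pairing, 2 that fell and 0 that rose, while 776 genes had an unadjusted p under 0.05, DESeq2 called 21 and limma on log2 FPKM called 1. No gene was left without any 1 of the 3 libraries with negative siRNA and DMSO, without replicate 1 or 2 of the group with TUNAR siRNAs and DMSO, or without replicate 2 of the group with negative siRNA and 1-AKP, and 1 was left without replicate 3 of either of the last 2 groups. Passage 74 alone, with 2 libraries per group, gave 0 genes, passage 75 has 1 library per group and no test, and passage as a covariate gave 2.

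Libraries with the same replicate number deviated together in this comparison. The block fit takes the same shift of a number in both treatments, although pairing across treatments did not meet the rule. With the number as a block 488 genes changed, 273 up and 215 down, both genes above among them. The median size of these changes was 0.22 on the log2 scale. IAPP, the islet amyloid peptide co-secreted with insulin, fell in the 3 pairs (-0.36, SE 0.043, adjusted p = 1.18e-06), from 112 ± 21.4 to 87.2 ± 15.1 CPM. IGFALS, a subunit of circulating insulin-like growth factor complexes, TAS1R3, a sweet taste receptor subunit, and FER1L5, a member of the ferlin family, fell by 0.59, 0.54 and 0.71 (adjusted p = 4.08e-05, 2.83e-05 and 0.00229). TCF4, a basic helix-loop-helix transcription factor that is a different gene from TCF7L2, rose by 0.54 (SE 0.087, adjusted p = 0.000156). The calls of these 5 genes, of SYPL1 and of B4GALT4 remained when any 1 replicate number was left out. The risen genes named by the rule also included RGS7BP at 0.83, RGS9 at 0.67, ITGBL1 at 0.66, GPR119, a lipid-sensing receptor of beta cells, at 0.65, SERTM2 at 0.64, RGMA at 0.63, LRRC4B at 0.62, BAALC at 0.56 and ASIC4, an ion channel subunit, at 0.53, and the fallen ones SAPCD1 at -1.26. Each of these 10 lost its call without at least 1 replicate number, and 38 of the 49 genes named from this fit did (21, 36 and 28 without replicate 1, 2 and 3). The block count was 327, 122 and 243 without replicate 1, 2 and 3 in turn, and limma on log2 FPKM with the block called 142, 51 up and 91 down. With library size as the only scaling the block split was 223 up and 254 down of 477. The 3′UTRs of IAPP, PDX1, UHRF1 and DKK3 hold 1 kind of the 7-base sequences found in SYPL1, and those of NKX6-1, CHGB, CALR, CD68, RYR2, MKI67, IGFALS, TAS1R3 and FER1L5 hold none. At least 1 kind is held by 25.2% of all genes with an annotated 3′UTR.

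Of the beta-cell transcription factors, 2 of the 21 tested fell with TUNAR siRNAs in the block fit and 0 rose. They were NKX6-1 (-0.22, SE 0.041, adjusted p = 0.00127), a factor of beta-cell identity, and PDX1 (-0.14, adjusted p = 0.00409), the pancreatic and beta-cell master factor. The NKX6-1 call ended without replicate 3 (adjusted p = 0.0563), and the PDX1 call without replicate 2 or 3 (highest adjusted p = 0.135). Among 33 insulin secretion genes, IAPP and the granule protein gene CHGB (-0.12, adjusted p = 0.00584; 0.228 without replicate 2) fell and 0 rose, with 6 risen and 4 fallen when adjusted over the list alone. INS, the insulin gene, stood at 10620 ± 1321 CPM and 11180 ± 1547 CPM (log2 fold change 0.07 in both fits, adjusted p = 0.17 with the block). DKK3, a member of the Dickkopf family of secreted Wnt modulators, rose by 0.34 (SE 0.069, adjusted p = 0.00248; 0.0942 without replicate 2), the only called member of the 3 tested secreted Wnt antagonists. MKI67, a proliferation marker, rose by 0.14 (adjusted p = 0.0051; 0.0873 at most without replicate 2 or 3), and 2 of 28 G2/M genes rose, MKI67 and TOP2A, and 0 fell. In S phase, UHRF1, a factor of DNA methylation maintenance, fell by 0.29 (adjusted p = 0.000893; 0.109 without replicate 2), with CCNE1 the other of 2 fallen among 28. The TOP2A and CCNE1 calls ended without any 1 replicate number. EZH2, CTNNB1, GSK3A, GSK3B, AXIN2 and MAFA changed by -0.03, 0.05, 0.02, 0.08, 0.07 and -0.13 in the block fit, none past the threshold. Without the block none of the 11 focus genes tested beside TUNAR passed in edgeR, with adjusted p from 0.844 to 1.

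Neural genes rose as a list with TUNAR siRNAs in DMSO (camera adjusted p = 0.00809 without the block and 0.0207 with it), calls lost at adjusted p = 0.956 and 0.731 with an estimated correlation. With the block, 3 of its 17 members rose and 0 fell: DCX, a microtubule protein of young neurons (0.24, adjusted p = 9.73e-05), STMN2, a tubulin-binding protein of neurites (0.20, adjusted p = 0.000199), and SOX11 (0.17, adjusted p = 0.0382; 0.358 at most without replicate 2 or 3). The DCX and STMN2 calls remained without any 1 replicate number. Adjusted over the list alone, 2 members rose without the block and 6 with it. The unfolded protein response list rose with the block (adjusted p = 0.033; adjusted p = 0.731 with an estimated correlation), with 5 risen and 1 fallen of 25 and 5 and 2 adjusted over the list alone. Its risen members included the endoplasmic reticulum chaperones and oxidoreductases PDIA4 (0.15), MANF (0.22), HSPA5 (0.13) and PDIA6 (0.11). The PDIA4 call remained without any 1 replicate number, the MANF call ended without replicate 1 (adjusted p = 0.0798), and the other 2 without each replicate. The glycolysis and hypoxia list fell with the block (adjusted p = 0.033; adjusted p = 0.731 with an estimated correlation), with 0 risen and 3 fallen of 21, the same when adjusted over the list alone. The 3 were GAPDH (-0.10), the lactate transporter gene SLC16A3 (-0.34) and VEGFA (-0.10), and each lost its call without at least 2 of the 3 replicate numbers.

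RYR2, the calcium release channel of the endoplasmic reticulum, rose by 0.47 (SE 0.073, adjusted p = 8.22e-05) from 20.9 ± 4.55 to 28.9 ± 4.56 CPM, and its call remained without any 1 replicate number. Of the 14 genes of endoplasmic reticulum calcium handling, RYR2 rose while CALR, a luminal calcium-binding chaperone (-0.12), and ORAI3, a plasma membrane calcium channel subunit (-0.27), fell. CD68, a lysosomal glycoprotein used as a macrophage marker, fell by 0.47 (adjusted p = 0.00164; 0.0598 without replicate 2), 1 of 5 endothelial and blood markers. Of the Wnt ligands and receptors, ROR2 (-0.18) and WNT5B (-0.31) fell and 0 rose of 18. DPP4 (-0.12) was 1 fallen of 9 markers of other islet cells, KRT19 (0.21) 1 risen of 6 duct and acinar markers and MSMO1 (-0.14) 1 fallen of 24 cholesterol genes. The calls in this paragraph other than that of RYR2 ended without at least 1 replicate number. Of the 30 lists, 15 had 0 called members with the block, and the smallest camera adjusted p of lists that did not pass was 0.0744 with the block and 0.119 without it. Lists whose median, mean and test differed in sign without the block were the Wnt target, S-phase, beta-cell factor, interferon, fatty acid, p53, immediate early, histone and TUNAR neighbour lists, all with a median between -0.02 and 0.05.

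The same siRNA comparison in 1-AKP-treated cells asks which genes depend on TUNAR in the presence of 1-AKP. Without pairing no gene passed the threshold: edgeR called 0 genes, 743 had an unadjusted p under 0.05, DESeq2 called 15 and limma on log2 FPKM called 3. The smallest adjusted p was 0.0872, for B4GALT4 (-0.49, from 77.8 ± 4.24 to 55.5 ± 1.67 CPM), and SYPL1 stood at -0.50 (adjusted p = 0.102). Leaving out replicate 1 of the group with TUNAR siRNAs and DMSO gave 3 genes, and leaving out replicate 3 of the group with TUNAR siRNAs and 1-AKP gave 1. Passage 74 alone gave 0 genes, passage 75 has no test, and passage as a covariate gave 0. With the block 443 genes changed, 231 up and 212 down. SYPL1 (-0.50, adjusted p = 0.0107), B4GALT4 (-0.49, adjusted p = 5.57e-07) and IAPP (-0.35, SE 0.05, adjusted p = 3.21e-05) fell here as in DMSO, and RYR2 (0.51, SE 0.072, adjusted p = 2.18e-05), TCF4 (0.52, adjusted p = 0.00137) and DKK3 (0.33, SE 0.071, adjusted p = 0.00499) rose. SYPL1, B4GALT4 and TCF4 are given here because they were named in DMSO. The largest changes named by the rule were RGS9 at 1.03, SLC26A4, the anion exchanger pendrin, at 0.98, SHISA6, an auxiliary subunit of glutamate receptors, at 0.97, ITGBL1 at 0.91 and RNF152 at 0.83 among the risen, and ODAPH at -0.82 and PRDM16, a zinc finger transcription factor, at -0.64 beside TUNAR among the fallen. Of the 34 genes named by the rule from this fit, CD68, DCX, IAPP, RYR2 and STMN2 kept their call without any 1 replicate number and 29 did not (18, 25 and 19 calls ended without replicate 1, 2 and 3). The block count was 306, 130 and 223 without replicate 1, 2 and 3 in turn, and limma on log2 FPKM with the block called 119, 44 up and 75 down. With library size as the only scaling the block split was 229 up and 226 down of 455. Long genes tended to have higher fold changes than short ones with TUNAR siRNAs, with a rank correlation of fold change with length of 0.13 in DMSO and 0.106 in 1-AKP across genes, which are not independent replicates.

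By list, the glycolysis and hypoxia genes fell in 1-AKP with TUNAR siRNAs (camera adjusted p = 0.00228, and 0.000697 with the block), although 0 of 21 passed singly. Adjusted over the list alone, 1 fell without the block and 9 with it, and the estimated correlation gave adjusted p = 0.846 and 0.355. Neural genes rose (0.00228, and 0.00519 with the block; adjusted p = 0.846 and 0.355 with an estimated correlation). With the block 3 of 17 rose and 0 fell, namely DCX (0.22), STMN2 (0.19) and SOX11 (0.20), and adjusted over the list alone 4 rose without the block and 5 with it. The block fit also gave higher unfolded protein response genes (adjusted p = 0.0464; 2 risen, PDIA4 and HSPA5, and 0 fallen of 25), lower ribosomal protein genes (adjusted p = 0.0461; 0 of 36 called, median -0.04; without the block the adjusted p went from 0.0635 to 0.53 after removal of the length trend, at a median of -0.02) and higher histone genes (adjusted p = 0.0482; 0 of 8 called), each with adjusted p = 0.745 with an estimated correlation. NKX6-1 (-0.18, adjusted p = 0.019; 0.396 at most without replicate 1 or 2) and PDX1 (-0.15, adjusted p = 0.00269; 0.105 without replicate 3) were the 2 fallen among 21 beta-cell factors. In insulin secretion IAPP and CHGB (-0.11) fell and CACNA1C, the pore of an L-type calcium channel (0.20), rose. CALR (-0.16) fell and RYR2 and CANX (0.10) rose in calcium handling. UHRF1 (-0.32) fell in S phase and MKI67 (0.15, adjusted p = 0.00278) rose in G2/M. Single fallen members were CD68 (-0.45, adjusted p = 0.00145), DPP4 (-0.17), ROR2 (-0.16), MSMO1 (-0.11), MX2 (-0.31), CDKN2B (-0.22), SDHC (-0.13) and SYNE3 (-0.60), the last a neighbour of the TUNAR locus. INS (0.07, adjusted p = 1), EZH2, CTNNB1, GSK3A, GSK3B, AXIN2 and MAFA did not pass in either fit. Secreted Wnt antagonists, beta-cell factors, insulin secretion, pluripotency, interferon and immediate early lists differed in sign between median, mean and test, with medians between -0.04 and 0.05.

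**Figure D3:**
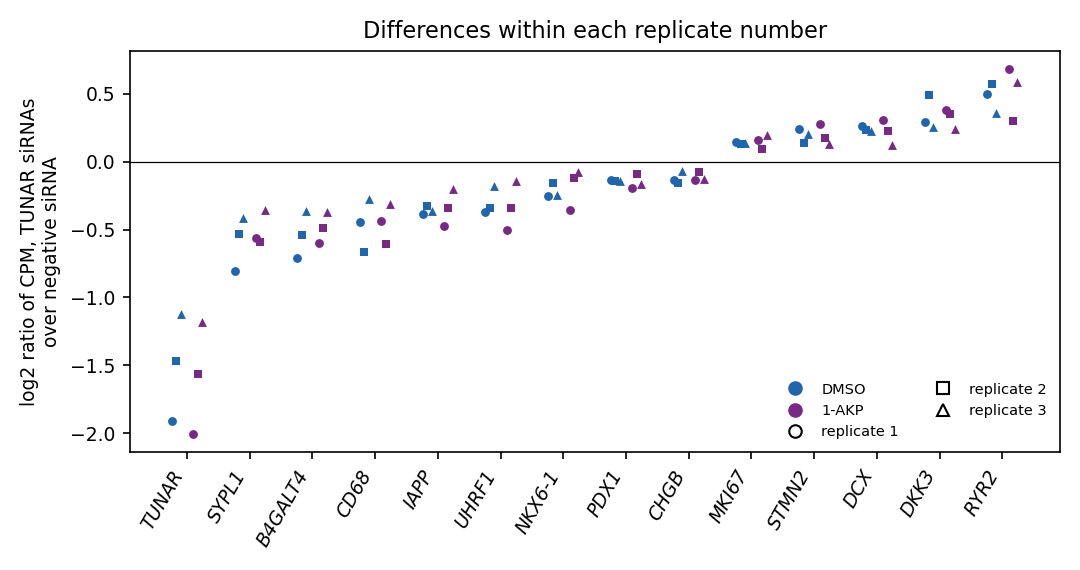
Log2 ratio of CPM with TUNAR siRNAs over negative siRNA (vertical axis) for 14 genes (horizontal axis), 1 point per replicate number, blue in DMSO and purple in 1-AKP. The genes were picked from the named genes called in a block fit, and such a call favours ratios of the same sign. For each gene shown the 3 ratios have the same sign in both treatments. Some named genes not shown have mixed signs, such as SHISA6 in DMSO and ORAI3 in 1-AKP. The ratios of TUNAR run from -1.91 to -1.13 in DMSO and from -2.01 to -1.18 in 1-AKP.

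Both siRNA comparisons share no library. Across the 15990 genes their log2 fold changes correlated at Pearson's r = 0.185 (SE 0.162 from leaving out libraries) and Spearman's rho = 0.35, and 65.5% had the same sign; genes are not independent replicates. Over genes with at least 50 counts in 3 libraries r was 0.432. The r of all 15990 genes lay between -0.002 and 0.154 in the 12 fits without 1 library, with the values nearest to the whole set without replicate 2 of negative siRNA with DMSO (0.154), of TUNAR siRNAs with DMSO (0.139) or of negative siRNA with 1-AKP (0.138). In the block fits, 133 genes rose in both and 116 fell in both, where independent lists of these sizes would share 3.94 and 2.85. Both comparisons use the same estimate of spread for a gene, so genes with a low estimate are more easily called in both. The values for independent lists are therefore not the overlap under chance. Of the genes called in DMSO, 98.2% of the risen and 99.1% of the fallen had the same sign in 1-AKP. The test of the difference between the siRNA effects in 1-AKP and in DMSO, which is also the difference between the 1-AKP effects with each siRNA, called 0 genes. By edgeR 170 genes had an unadjusted p under 0.05, DESeq2 called 0, limma on log2 FPKM called 2, and the block fit called 0 with 514 genes at an unadjusted p under 0.05. TUNAR itself had a difference of -0.09 (SE 0.362, adjusted p = 1). No list passed for this difference, with a smallest adjusted p of 0.759, and 0.285 with the block.

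1-AKP with negative siRNA was compared with DMSO to ask what this compound alone does in these cells. GSK3 activity was not measured here, so other actions of 1-AKP cannot be told apart from GSK3 inhibition. FBXO32, the F-box subunit of a ubiquitin ligase of muscle atrophy, fell from 4.23 ± 0.447 to 0.781 ± 0.223 CPM, with a fitted fall of 5.37-fold. FRAT1 and FRAT2, which encode GSK3-binding proteins, fell from 4.16 ± 0.661 to 1.10 ± 0.0743 CPM and from 12.6 ± 1.05 to 5.76 ± 0.820 CPM. NKX2-2, a beta-cell transcription factor, fell from 116 ± 9.41 to 66.5 ± 2.70 CPM and NKX6-1 from 127 ± 6.47 to 88.5 ± 0.507 CPM. LDHA, the lactate dehydrogenase subunit, rose from 209 ± 7.35 to 305 ± 15.6 CPM, and PTGS2, the inducible cyclooxygenase, rose from 109 ± 14.3 to 252 ± 8.71 CPM. INS stayed within the spread between replicates, at 10810 ± 1249 CPM against 10620 ± 1321 CPM (log2 fold change 0.03, SE 0.148, adjusted p = 0.95).

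In total 1168 genes changed with 1-AKP and negative siRNA, 7.3% of those tested, 566 up and 602 down, and 46 of them by at least 1 on the log2 scale (12 up, 34 down). The median size of the called changes was 0.30. With library size as the only scaling the split was 414 up and 702 down of 1116. Passage 74 alone gave 51 genes, passage 75 has no test, and passage as a covariate gave 1535; without the replicate 1 libraries of all groups the count was 2559. It was 655, 554 and 606 without replicate 1, 2 or 3 of negative siRNA with DMSO, and 498 and 492 without replicate 2 or 3 of negative siRNA with 1-AKP. Short genes tended to have higher fold changes than long ones: the rank correlation of fold change with gene length across genes, which are not independent replicates, was -0.17, and 822 of the called genes remained after the length trend of each library was removed. Of the 76 called genes that the rule names here, 43 kept their call without any 1 of the 12 libraries, and the others are marked where the text gives them. The named calls that ended numbered 22, 27 and 20 without replicate 1, 2 and 3 of negative siRNA with DMSO, 13, 29 and 27 without those of negative siRNA with 1-AKP, 6, 7 and 9 without those of TUNAR siRNAs with DMSO, and 10 and 9 without replicates 2 and 3 of TUNAR siRNAs with 1-AKP.

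Among the fallen genes named by the rule for the largest folds (mean log2 CPM of at least 1, no overlap between groups), those that kept their call without any 1 library were, after FBXO32 (-2.43, SE 0.24, adjusted p = 0.000141), ABTB1 (-2.11, SE 0.176, adjusted p = 5.77e-05), FRAT1 (-1.92, SE 0.204, adjusted p = 0.000245), FOXO4, a forkhead transcription factor (-1.77, SE 0.152, adjusted p = 7.42e-05), RGS9, a regulator of G-protein signalling (-1.74, adjusted p = 0.00201), KLHL24, a ubiquitin ligase adaptor (-1.64, adjusted p = 0.00058), BCAS3 (-1.59, adjusted p = 0.00137), COQ8A, a factor of coenzyme Q synthesis (-1.26, adjusted p = 5.86e-06), and BTN3A1, a butyrophilin (-1.24, adjusted p = 0.0043). KLHL24 fell from 43.3 ± 6.62 to 13.9 ± 3.14 CPM, FOXO4 from 5.62 ± 0.181 to 1.65 ± 0.255 CPM, and COQ8A from 40.9 ± 3.17 to 17.1 ± 0.104 CPM. Among the risen, SECTM1, a secreted and membrane protein of immune signalling, gained 1.76 (SE 0.305, adjusted p = 0.0074) from 6.33 ± 1.45 to 21.4 ± 6.06 CPM. SLC7A7, a subunit of a cationic amino acid transporter, rose by 1.34 (SE 0.147, adjusted p = 0.000297) and LRAT, the enzyme that esterifies retinol, by 1.24 (SE 0.209, adjusted p = 0.0045). PTGS2 rose by 1.21 (SE 0.087, adjusted p = 5.22e-05) and FLRT3, a transmembrane adhesion protein, by 0.99 (SE 0.092, adjusted p = 0.000106). SULF2, an extracellular heparan sulfate sulfatase, had a change of 2.00 (SE 0.53, adjusted p = 0.0496), from 4.16 ± 1.85 to 16.6 ± 7.26 CPM, and its call remained in 2 of the 12 fits without 1 library. Calls that ended without some libraries of the groups compared were those of NRP1, a semaphorin and VEGF co-receptor (1.27; highest adjusted p = 0.073, without replicate 2 or 3 of the DMSO group), TFAP2B (1.27), CSGALNACT1 (1.15) and NYNRIN (-1.38).

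Among 21 beta-cell transcription factors, 5 fell and 0 rose with 1-AKP and negative siRNA, and 8 fell when adjusted over the list alone. The list was lower as a whole (median -0.24, camera adjusted p = 5.5e-06), a call lost at adjusted p = 0.434 with an estimated correlation. NKX2-2 fell by 0.80 (SE 0.095, adjusted p = 0.000532), NKX6-1 by 0.52 (SE 0.073, adjusted p = 0.00159), MLXIPL, a glucose-responsive factor, by 0.52 (SE 0.085, adjusted p = 0.0037) and PAX6, an islet cell factor, by 0.29 (SE 0.043, adjusted p = 0.00201). PDX1 stood at -0.12 (adjusted p = 0.247) and MAFA at -0.43 (SE 0.31, adjusted p = 0.494). Of 33 insulin secretion genes 6 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.176). GIPR, the receptor of the incretin GIP, fell by 0.55 (SE 0.089, adjusted p = 0.00356) from 26.7 ± 2.28 to 18.2 ± 0.679 CPM, CACNA1C by 0.26, ERO1B, an oxidase of disulfide bond formation, by 0.29, and UCN3, a peptide hormone of mature beta cells, by 0.62 (adjusted p = 0.0171; 0.0794 at most, without replicate 2 of either group compared).

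Of 15 Wnt target genes 1 fell and 0 rose with 1-AKP and negative siRNA, also when adjusted over the list alone, and the list was lower (median -0.22, camera adjusted p = 0.0277; adjusted p = 0.267 with an estimated correlation). The member that fell was KREMEN1, known as a receptor of the Wnt antagonist DKK1 rather than as a mediator of Wnt signals (-0.51, SE 0.077, adjusted p = 0.00234). AXIN2, a feedback target of beta-catenin, stood at 9.99 ± 1.11 and 9.32 ± 0.859 CPM (-0.10, SE 0.133, adjusted p = 0.746), CCND1 did not pass the filter, and 1 other focus gene was not analysed here. The destruction complex list had 2 fallen of 14 and 0 risen, FRAT1 and FRAT2 (-1.13, SE 0.118, adjusted p = 0.000215), which bind GSK3 (camera adjusted p = 0.392). CTNNB1, the gene of beta-catenin, changed by -0.18 (SE 0.073, adjusted p = 0.191), GSK3A by 0.12 (adjusted p = 0.212) and GSK3B by 0.00 (adjusted p = 0.999). Of 18 Wnt ligands and receptors 3 fell and 0 rose (camera adjusted p = 0.176), namely the receptors ROR1 (-0.58) and FZD3 (-0.24) and the ligand WNT4 (-0.35), whose calls remained in 10, 5 and 6 of the 12 fits without 1 library. DKK3 stood at -0.08 (SE 0.191, adjusted p = 0.876), and none of the 3 secreted Wnt antagonists was called (median -0.001, mean 0.12, camera upward with adjusted p = 0.942).

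Ribosomal protein genes rose with 1-AKP as a list: 22 of 36 rose and 0 fell, with 33 risen when adjusted over the list alone (median 0.18, camera adjusted p = 6.32e-18; adjusted p = 0.00658 with an estimated correlation, a call that ended at 0.065 with the replicate block). RPS6 rose from 568 ± 10.1 to 669 ± 11.1 CPM (0.24, adjusted p = 0.00187), and RPL27, RPS15 and RPL38 rose by 0.23, 0.25 and 0.25. After removal of the length trend the median was 0.11 and the adjusted p 4.49e-09. Glycolysis genes also rose, 10 of 21 with 0 fallen, and 13 risen with 1 fallen adjusted over the list alone (median 0.22, camera adjusted p = 6.12e-06; adjusted p = 0.21 with an estimated correlation). LDHA rose by 0.54 (SE 0.066, adjusted p = 0.00058), PGK1 by 0.27, ALDOA by 0.37 and PFKM by 0.25, the last with adjusted p = 0.0515 without replicate 3 of negative siRNA with 1-AKP. Of 33 genes of oxidative phosphorylation 4 rose and 0 fell, 10 risen adjusted over the list alone (median 0.12, camera adjusted p = 5.5e-06; adjusted p = 0.0999 with an estimated correlation, and 0.0208 at a median of 0.08 after removal of the length trend, or 0.332 with both). They were COX5A (0.22), ATP5F1C (0.17), ATP5F1B (0.12) and NDUFA9 (0.20), whose calls remained in 8, 3, 1 and 2 of the 12 fits. The unfolded protein response list rose (median 0.16, camera adjusted p = 0.000722; adjusted p = 0.325 with an estimated correlation) with 7 risen and 1 fallen of 25, and 11 and 1 adjusted over the list alone. MANF rose by 0.34 (adjusted p = 0.00747), HYOU1 by 0.24 and PDIA4 by 0.21 (adjusted p = 0.0619 at most, without replicate 2 or 3 of negative siRNA with 1-AKP), all endoplasmic reticulum proteins, while HERPUD1, a factor of protein degradation at that organelle, fell by 0.30. In calcium handling CANX, a lectin chaperone (0.33, adjusted p = 0.000418), and ITPR3, an inositol trisphosphate receptor (0.34, adjusted p = 0.00173), were 2 risen of 14 with 0 fallen (camera adjusted p = 0.275).

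Cell cycle genes changed little with 1-AKP and negative siRNA. MKI67 stood at 0.05 (adjusted p = 0.809) and EZH2, a histone methyltransferase, at -0.04 (adjusted p = 0.831). No gene of 28 in G2/M was called (median -0.02, camera upward with adjusted p = 0.959). The S-phase list was higher (median 0.09, camera adjusted p = 0.0322; adjusted p = 0.645 with an estimated correlation), with 2 risen and 1 fallen of 28, the same numbers as adjusted over the list alone. FEN1 rose (0.25) and E2F2 fell (-0.25), and their calls remained in 8 and 7 of the 12 fits without 1 library. CCND3, cyclin D3, rose by 0.21 (adjusted p = 0.0654 at most, without replicate 2 of either group compared), 1 of 14 cyclins and inhibitors and 2 adjusted over the list alone. In polyadenylated RNA, the tested histone genes (8 of 18 entries) were lower (median -0.54, camera adjusted p = 0.00862, and 0.325 with an estimated correlation). H2BC21 (-0.77, adjusted p = 0.0127, kept in 9 of the 12 fits) was the 1 fallen of 8 with 0 risen, and 2 fell adjusted over the list alone. RNA without a poly(A) tail was not sequenced, so total histone RNA was not measured. JARID2, a Polycomb cofactor, fell by 0.60 (SE 0.097, adjusted p = 0.00364) and CBX7 by 0.87 (kept in 4 of the 12 fits), 2 fallen and 0 risen of 19 Polycomb genes, and 4 fallen adjusted over the list alone (camera adjusted p = 0.074).

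Of 17 neural genes 4 fell and 1 rose, and 5 and 3 adjusted over the list alone (median -0.17, camera adjusted p = 0.0835). DCX fell by 0.41 (SE 0.068, adjusted p = 0.00433) and ELAVL4, a neuronal RNA-binding protein, by 0.62 (adjusted p = 0.00788), and SOX4 (-0.54) and STMN2 (-0.21) fell with calls kept in 7 and 3 of the 12 fits. In glycogen and insulin signalling, IRS2, an insulin receptor adaptor, fell by 0.43 (adjusted p = 0.00722), while GYG1 (0.45), which primes glycogen synthesis, and PYGB (0.22), which breaks glycogen down, rose with calls kept in 9 and 7 fits (2 risen and 1 fallen of 12). SESN1, a stress-responsive regulator of mTORC1, fell by 0.32 (adjusted p = 0.00737), 1 of 16 p53 targets. ATG2B, an autophagy lipid transfer protein, fell by 0.45 (adjusted p = 0.00722), 1 of 11 TUNAR neighbours. DHCR7 (0.25, adjusted p = 0.00885) and NSDHL (0.30, kept in 7 fits), enzymes of cholesterol synthesis, were 2 risen of 24. Of 18 apoptosis genes CYCS (0.20) rose and APAF1 (-0.44) fell, of 18 immediate early genes FOSL2 (0.72) rose and IER2 (-0.28) and NR4A2 (-0.87) fell, SCD (0.13) was 1 risen of 11 fatty acid genes and RSAD2 (-0.52) 1 fallen of 18 interferon genes. The calls in the last sentence remained in 9, 9, 8, 8, 3, 1 and 4 of the 12 fits, in that order. The counts of the lists in this paragraph after the neural genes were the same adjusted over the list alone, and their camera adjusted p ran from 0.327 to 0.634. Markers of other islet cells (9 tested), duct and acinar cells (6), fibroblast and stellate cells (4), endothelial and blood cells (5) and pluripotency genes (7) had 0 called members and camera adjusted p from 0.445 to 0.901. The median and the mean differed in sign for the fibroblast (-0.03 and 0.25) and pluripotency (-0.04 and 0.02) lists.

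**Figure D4:**
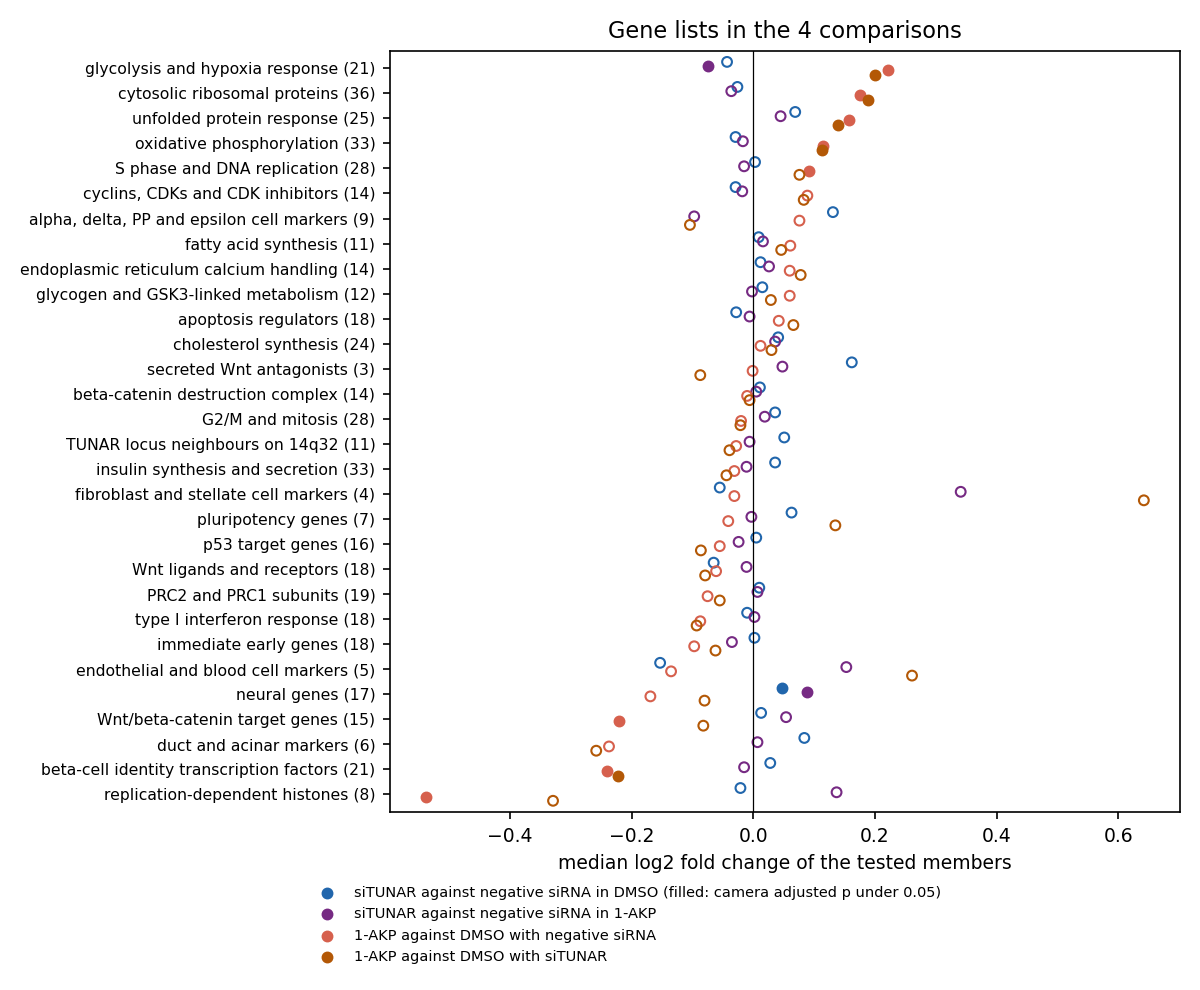
Median log2 fold change (horizontal axis) of the tested members of the fixed gene lists (vertical axis) in each comparison, with filled points where camera's adjusted p with the preset correlation was under 0.05. With 1-AKP and negative siRNA, the medians of the ribosomal protein, glycolysis and beta-cell factor lists are 0.18, 0.22 and -0.24.

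1-AKP was also compared with DMSO in cells with TUNAR siRNAs, to ask what 1-AKP does when TUNAR is low. FBXO32 fell from 3.93 ± 0.644 to 0.870 ± 0.236 CPM (-2.17, SE 0.238, adjusted p = 0.00026). ABTB1 (-2.06, adjusted p = 5.04e-05), FRAT1 (-1.60, adjusted p = 0.000636), KLHL24 (-1.57, adjusted p = 0.000678) and FRAT2 (-1.12, adjusted p = 0.000213) fell as well. SECTM1 rose by 1.88 (SE 0.311, adjusted p = 0.00542), LRAT by 1.70 (SE 0.206, adjusted p = 0.000508), NRP1 by 1.51 (SE 0.267, adjusted p = 0.00544) and SLC7A7 by 1.5 (SE 0.15, adjusted p = 0.000172). NKX2-2 fell by 0.87 (adjusted p = 0.00026) and NKX6-1 from 109 ± 8.53 to 78.2 ± 7.53 CPM (-0.48, adjusted p = 0.00254). LDHA rose from 176 ± 15.9 to 254.7 ± 14.4 CPM (0.53, adjusted p = 0.000636). SULF2 (2.07, adjusted p = 0.0369) and DEPTOR, an inhibitor of mTOR (-1.69, SE 0.46, adjusted p = 0.0488), kept their calls in 6 and 2 of the 12 fits without 1 library. INS stood at 0.02 (adjusted p = 0.961), PDX1 at -0.13 (adjusted p = 0.208), CTNNB1 at -0.22 (adjusted p = 0.0885), AXIN2 at -0.18 (adjusted p = 0.483), DKK3 at -0.09 (adjusted p = 0.859), MAFA at -0.43 (adjusted p = 0.492) and MKI67 at 0.06 (adjusted p = 0.75); EZH2, GSK3A and GSK3B were at 0.00, 0.08 and -0.05, not past the threshold.

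With TUNAR siRNAs 1201 genes changed with 1-AKP, 7.51% of those tested, 595 up and 606 down, 49 of them by at least 1 on the log2 scale (20 up, 29 down). With library size as the only scaling the split was 495 up and 690 down of 1185. Passage 74 alone gave 67 genes, passage 75 has no test, and passage as a covariate gave 1628; without the replicate 1 libraries of all groups the count was 2769. It was 786, 511 and 662 without replicate 1, 2 or 3 of TUNAR siRNAs with DMSO and 643 and 562 without replicate 2 or 3 of TUNAR siRNAs with 1-AKP. Of 59 called genes named by the rule, 33 kept their call without any 1 library and 26 did not. The named calls that ended numbered 15, 25 and 21 without replicate 1, 2 and 3 of TUNAR siRNAs with DMSO, 5, 16 and 22 without those of TUNAR siRNAs with 1-AKP, 1, 10 and 6 without those of negative siRNA with DMSO, and 11 and 3 without replicates 2 and 3 of negative siRNA with 1-AKP. The rank correlation of fold change with gene length was -0.185. This comparison shares no library with the one with negative siRNA. Called in both were 413 risen and 456 fallen genes, where independent lists would share 21.1 and 22.8, and 0 genes were called in opposite directions. Here too both comparisons use the same estimate of spread for a gene, so the values for independent lists are not the overlap under chance. The log2 fold changes correlated across genes at r = 0.492 (SE 0.132) and rho = 0.642, with the same caution that genes are not independent replicates. Over genes with at least 50 counts in 3 libraries r was 0.836. The r of all genes was 0.285 without replicate 1 of negative siRNA with DMSO, 0.282 and 0.322 without replicate 2 or 3 of TUNAR siRNAs with DMSO, 0.279 without replicate 3 of negative siRNA with 1-AKP, and 0.322 without replicate 1 of TUNAR siRNAs with 1-AKP.

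By list, the beta-cell factors were lower with 1-AKP and TUNAR siRNAs (median -0.22, 8 fallen and 0 risen of 21, 9 fallen adjusted over the list alone, camera adjusted p = 1.55e-06; adjusted p = 0.398 with an estimated correlation). Ribosomal protein genes rose (median 0.19, 21 risen and 0 fallen of 36, 31 risen adjusted over the list alone, adjusted p = 1.25e-16; adjusted p = 0.0085 with an estimated correlation, a call that ended at 0.0776 with the replicate block), with RPS6 at 0.27, RPS29 at 0.24, RPL27 at 0.24 and RPL19 at 0.20. Oxidative phosphorylation genes rose (median 0.11, 2 risen of 33 and 11 adjusted over the list alone, adjusted p = 2.62e-06; adjusted p = 0.0862 with an estimated correlation, and 0.0248 at a median of 0.08 after removal of the length trend, or 0.432 with both), with COXFA4 (0.30) and COX5A (0.19) called and kept in 7 and 5 of the 12 fits. Glycolysis genes rose (median 0.20, 8 risen and 0 fallen of 21, 13 and 2 adjusted over the list alone, adjusted p = 0.000187), as did unfolded protein response genes (median 0.14, 6 risen and 1 fallen of 25, 11 and 1 adjusted over the list alone, adjusted p = 0.00103), each with adjusted p = 0.398 with an estimated correlation. PGK1, GAPDH and ENO2 rose by 0.23, 0.31 and 0.30, and PDIA4 (0.20), HYOU1 (0.21), ATF4 (0.18) and HERPUD1 (-0.24) changed with calls kept in 9, 10, 7 and 10 fits. The Wnt target, S-phase and histone lists, which passed with negative siRNA, had an adjusted p of 0.166 each, with KREMEN1 fallen (-0.31), FEN1 risen (0.23) and H2BC21 fallen (-0.58) as their called members, kept in 8, 4 and 6 fits; after removal of the length trend the histone list passed here too (adjusted p = 0.0256; adjusted p = 0.432 with an estimated correlation). No list differed between the siRNAs in the test of the difference given above.

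Other called members with 1-AKP and TUNAR siRNAs were, in the beta-cell lists, PAX6 (-0.27), MLXIPL (-0.40), GIPR (-0.62, adjusted p = 0.00161), ERO1B (-0.31) and CACNA1C (-0.17). DCX fell by 0.43 and ELAVL4 by 0.51, while SYP, a synaptic vesicle protein, rose by 0.19, with 5 fallen and 1 risen of 17 neural genes and 6 and 2 adjusted over the list alone (camera adjusted p = 0.184). CANX (0.34) and ITPR3 (0.29) rose in calcium handling. ROR1 (-0.49) and WNT4 (-0.33) fell among the Wnt ligands and receptors, JARID2 (-0.52) and RNF2 (-0.31) among the Polycomb genes, and IRS2 fell (-0.39) while PYGB (0.27) and GYG1 (0.41) rose. CCND3 (0.23) and CDK4 (0.31) rose and CDKN2B (-0.26), an inhibitor of CDK4, fell. CYCS (0.20) rose and BCL2L11 (-0.20), a pro-apoptotic factor, fell. NR4A2 (-1.42, SE 0.246, adjusted p = 0.00492), SESN1 (-0.27) and ATG2B (-0.41) fell, and DHCR7 (0.24), NSDHL (0.29) and EBP (0.22) rose. Of these, the calls of MLXIPL, CACNA1C, ELAVL4, ROR1, WNT4, RNF2, GYG1, CDK4, CDKN2B, CYCS, BCL2L11, SESN1, DHCR7, NSDHL and EBP ended without at least 1 library. Insulin secretion genes had 3 fallen of 33 and 6 adjusted over the list alone, and cell-type marker, G2/M, secreted Wnt antagonist, pluripotency, interferon and fatty acid lists had 0 called members. The pluripotency list had a median of 0.14 and a mean of -0.02.

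**Figure D5:**
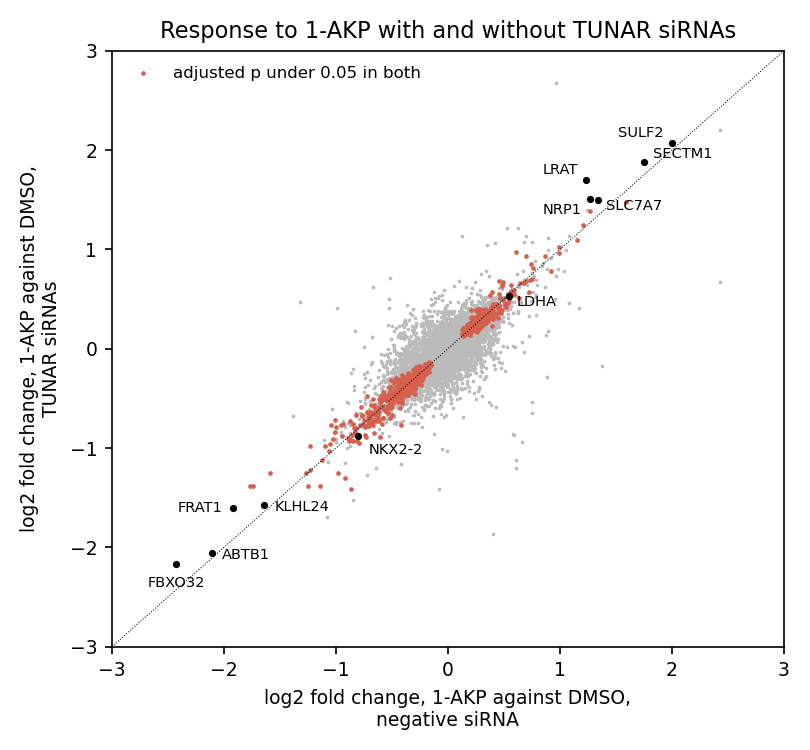
Log2 fold change with 1-AKP in cells with negative siRNA (horizontal axis) against that in cells with TUNAR siRNAs (vertical axis), 1 point per gene with a mean log2 CPM of at least 1 (13813 genes; 2 lie outside the axes). The 863 red and black points, some of them named, are genes called in the same direction in both comparisons, and 0 were called in opposite directions.

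Averaged over the other factor, the effects of TUNAR siRNAs and of 1-AKP had a Pearson's r of -0.001 across genes (SE 0.359; rho = -0.095), which are not independent replicates. It ran from -0.168 to 0.132 leaving out 1 library, and over genes with at least 50 counts in 3 libraries it was -0.111, so a correlation in either direction is not excluded. The covariance was -4.05e-05, within the range of -0.00415 to 0.00591 in 20 simulated sets of unchanged groups. In the averaged block fit 1373 genes changed with TUNAR siRNAs, 704 up and 669 down. NKX6-1 had negative estimates with TUNAR siRNAs and with 1-AKP, and DCX had estimates of opposite sign, 0.24 with TUNAR siRNAs in DMSO and -0.41 with 1-AKP and negative siRNA.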

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

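The fits without the replicate 1 libraries, with the length trend removed, and the alternatives of the block fits were chosen after the data were seen; the others were fixed before. Depth was even, from 15653786 to 15986834 expected counts per library, and how far it limits genes near the filter was not tested. In simulations at this depth and spread, the smallest changes tried were found in 22.4% of genes by the fit without pairing. Small effects of TUNAR siRNAs can therefore be missed without the block. For TUNAR siRNAs in DMSO, unchanged genes made up 16 of 189 simulated calls with the block and 1 of 112 without it. For 1-AKP with negative siRNA these were 20 of 188 and 0 of 119. Both shares with the block lay above the threshold on adjusted p, although the simulation favours that fit. Block calls can therefore include more false ones than the threshold states. Under DESeq2 size factors and library size, the median fold change of all genes lay farthest from 0 at -0.0256 (library size only, 1-AKP with negative siRNA). Of the called genes named with 1-AKP and negative siRNA (76) and with 1-AKP and TUNAR siRNAs (59), 62 and 42 kept their call with the length trend removed, 73 and 58 without replicate 1, and 8 and 8 in passage 74 alone. DESeq2 gave no adjusted p for FBXO32 and NR4A2 in either 1-AKP comparison. For every result below that moved or reversed, the cause was not tested, except that fits on fewer libraries have fewer degrees of freedom.

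The replicate numbers pair the siRNA libraries by the rule in the methods. For 1-AKP the correlations of same-numbered libraries were 0.427, 0.087 and 0.223 with negative siRNA and 0.407, 0.063 and 0.159 with TUNAR siRNAs. There the samples therefore share only a number. The highest correlation with another number was larger for replicate 2 with negative siRNA (0.157) and for replicates 2 and 3 with TUNAR siRNAs (0.181 each). For the other replicates it was smaller. Of the 12 libraries 11 correlated best with their own number. That search took in all other groups, the siRNA partner of the same treatment included, so it does not decide on pairing across 1-AKP. With the replicate block the counts were 488 and 443 for TUNAR siRNAs in DMSO and 1-AKP and 4285 and 4335 for 1-AKP with negative and TUNAR siRNAs, which include all 1168 and 1201 genes called without it, and TUNAR stood at -1.45 (adjusted p = 0.00248) and -1.55 (adjusted p = 0.000674). The difference of effects stayed at 0 calls with the block. Under the block the direction of 9 list tests that had not passed reversed, at medians of 0.004 for S phase, 0.028 for beta-cell factors, -0.005 for interferon, -0.001 for p53 and 0.05 for TUNAR neighbours (TUNAR siRNAs in DMSO), 0 for interferon (TUNAR siRNAs in 1-AKP), -0.001 for secreted Wnt antagonists and -0.022 for G2/M (1-AKP with negative siRNA), and 0 for insulin secretion (difference of effects). With library size only, the immediate early list (-0.002, TUNAR siRNAs in DMSO) and the G2/M list (-0.037, 1-AKP with TUNAR siRNAs) reversed. Limma on log2 FPKM with the block called 142 and 119 genes for TUNAR siRNAs in DMSO and 1-AKP. Leaving out 1 replicate number, the block counts ran from 122 to 327 and from 130 to 306. The other alternatives of the block fits gave between 463 and 538 genes in DMSO and between 411 and 503 in 1-AKP.

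For TUNAR siRNAs in DMSO (2 genes), the counts were 0 in passage 74, 0 in the 6 libraries alone, 0 with a fold minimum of 1 on the log2 scale, 21 with the DESeq2 Wald test, 1 with limma on log2(FPKM + 1), 1 with a pseudocount of 0.1, 0 with limma without a filter, 45 without replicate 1, and from 0 to 2 leaving out 1 library. For TUNAR siRNAs in 1-AKP (0 genes), they were 15 with DESeq2, 3 with limma, 2 with limma without a filter, 1 with edgeR without a filter, 45 without replicate 1, and from 0 to 3 leaving out 1 library. TUNAR passed in DESeq2 at -1.44 (adjusted p = 5.33e-05) in DMSO and -1.53 (adjusted p = 2.81e-06) in 1-AKP, and without replicate 1 at -1.30 (adjusted p = 6.23e-06) and -1.36 (adjusted p = 1.9e-07). In 1-AKP it ran from -1.78 to -1.31 leaving out 1 library (adjusted p from 0.0371 to 0.711). The difference of effects had 2 calls with limma, with and without its filter, and 0 under the other settings.

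For 1-AKP with negative siRNA (1168 genes), the counts were 51 in passage 74, 777 in the 6 libraries alone, 46 with the fold minimum, 2559 without replicate 1, and from 492 to 1389 leaving out 1 library. With TUNAR siRNAs (1201 genes), they were 67, 447, 49, 2769, and from 511 to 1284. Apart from the replicate block given above, all other settings stayed within 1.5 times, with 895 and 913 genes after removal of the length trend. The correlation of the siRNA effects (0.185) was -0.046 in passage 74, 0.432 with the stricter filter, -0.009 without replicate 1, and from -0.002 to 0.154 leaving out 1 library. That of the 1-AKP effects (0.492) was 0.248 in passage 74, 0.104 without a filter, 0.836 with the stricter filter, 0.294 with limma and a pseudocount of 0.1, 0.656 in the 6 libraries alone, 0.328 without replicate 1, and from 0.279 to 0.429 leaving out 1 library.

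Focus genes that reversed had not passed in any case. With 1-AKP and negative siRNA, these were GSK3B at 0 (passage as a covariate), 0.002 (DESeq2 size factors, the DESeq2 Wald test and the 6 libraries alone), 0 (no filter) and 0.055 (length trend removed); DKK3 at 0.002 (without replicate 1); EZH2 at 0.011 and AXIN2 at 0.072 (passage 74); and INS at -0.068 (length trend removed). With 1-AKP and TUNAR siRNAs, they were EZH2 at -0.011 (library size only), -0.001 (stricter filter), -0.009 (limma, with and without its filter), -0.01 (pseudocount 0.1) and -0.026 (without replicate 1); GSK3B at 0.007 and INS at -0.074 (length trend removed); and INS at -0.001 (the 3 limma settings). With TUNAR siRNAs in 1-AKP, they were CTNNB1 at -0.005 (the 3 limma settings) and -0.015 (without replicate 1); EZH2 at -0.009 and GSK3A at 0.013 (passage 74); and GSK3A at 0.008 and AXIN2 at 0.069 (without replicate 1).

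Leaving out 1 library, focus genes that crossed 0 for TUNAR siRNAs in DMSO ran from -0.082 to 0.038 (EZH2), -0.013 to 0.11 (CTNNB1), -0.013 to 0.045 (GSK3A), -0.045 to 0.183 (AXIN2), -0.007 to 0.182 (INS) and -0.299 to 0.076 (MAFA). In 1-AKP they ran from -0.026 to 0.038 (EZH2), -0.055 to 0.051 (CTNNB1), -0.042 to 0.01 (GSK3A), -0.007 to 0.088 (GSK3B), -0.085 to 0.028 (AXIN2), -0.029 to 0.204 (INS) and -0.32 to 0.134 (MAFA). For 1-AKP with negative siRNA they ran from -0.194 to 0.12 (DKK3), -0.084 to 0.023 (EZH2), -0.048 to 0.045 (GSK3B), -0.013 to 0.111 (MKI67) and -0.057 to 0.119 (INS). With TUNAR siRNAs they ran from -0.228 to 0.074 (DKK3), -0.042 to 0.062 (EZH2), -0.094 to 0.01 (GSK3B), -0.005 to 0.122 (MKI67) and -0.086 to 0.152 (INS).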

Other observations

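Tests chosen only after the result was seen were those of FOXO, NRF2 and aryl hydrocarbon receptor targets, of the FOXO list without its top fallen members, of Alu repeats, of the 7-base sequences in the TUNAR transcript, of passage, gene length and G6PC2 in replicate 1, and of other splits of the samples.

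FOXO target genes were lower with 1-AKP: of 21 tested, 8 fell with negative siRNA and 9 with TUNAR siRNAs, and the medians were -0.43 and -0.27. INSR, the insulin receptor gene (-0.49, adjusted p = 0.000129), RICTOR, a subunit of mTORC2 (-0.52, adjusted p = 0.000175), and PINK1, a mitochondrial kinase (-0.70, adjusted p = 0.00107), fell with negative siRNA beside FBXO32, KLHL24, IRS2, SESN1 and GABARAPL1. Lower FOXO transcription factor activity is a candidate explanation: the higher of both camera p-values was 2.38e-09, though p = 0.0619 with negative siRNA and 0.0553 with TUNAR siRNAs with an estimated correlation. Without the members already seen among the top fallen genes the higher p was 4.79e-07, and p = 0.106 with negative siRNA and 0.0918 with TUNAR siRNAs with an estimated correlation. That check left out FBXO32 and KLHL24 only. IRS2, SESN1 and BCL2L11 stayed in, although they had already been called as members of other lists, so the check is not free of genes seen before.

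NRF2 targets were higher with 1-AKP (median 0.23 with negative and 0.28 with TUNAR siRNAs), with 4 and 5 risen and 0 fallen of 20. GSR, the glutathione reductase gene (0.38, adjusted p = 0.00372 with negative siRNA), TALDO1, TKT and PGD rose in both, and TXN with TUNAR siRNAs only. GCLM (-0.17 with negative and -0.11 with TUNAR siRNAs) and GCLC (-0.13 and -0.19) had negative estimates, not past the threshold. The higher camera p was 0.000115, which goes with higher NRF2 activity as a possible explanation, and it was 0.08 with an estimated correlation. With TUNAR siRNAs the same list was lower with 0 of 20 members called, at camera adjusted p = 0.0481 in DMSO and 0.0163 in 1-AKP (p = 0.206 and 0.158 with an estimated correlation), and the call in DMSO ended after removal of the length trend (adjusted p = 0.115, and 0.0347 in 1-AKP). Lysosomal genes were higher with 1-AKP too, with 5 and 7 risen of 29 and LAMP1 at 0.29 with negative siRNA. Higher TFEB activity may account for this (higher camera p = 1.96e-05, and 0.295 with an estimated correlation). Ribosome biogenesis genes had a higher camera p of 0.000112 for higher MYC activity (0.359 with an estimated correlation), with 1 and 2 risen of 22. For aryl hydrocarbon receptor activation by 1-AKP the higher p was 0.141, with negative siRNA (median 0.39), and with TUNAR siRNAs p was 0.00432 (median 0.58; p = 0.02 with an estimated correlation). With 4 tested targets, of which 0 were called, this stays open.

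The first pattern weighed is the set of genes that fell with TUNAR siRNAs. Among the 7-base sequences in 3′UTRs, the one most associated with lower levels in DMSO, GAGGGTT, ranked 1 in 1-AKP too, over libraries not shared, as seed-matched off-target silencing by the siRNAs predicts. Both rankings are not independent, since the statistics of all sequences ranked correlated at 0.686 between treatments. A sequence tied to the shared fallen genes for another reason would also rank alike in both, so the repeat does not decide for off-target silencing. Picked in DMSO, GAGGGTT is in 27.3% of the genes that fell in the block fit in 1-AKP, against 8.2% of those that rose and 9.5% of all. SYPL1 and B4GALT4, which were part of the search, hold 7-base parts of both GAGGGTTA and TGATCATA. For GAGGGTT, Alu repeats as the source are argued against by a rank of 1 in both treatments without genes holding one. CACTGCA, 1 of the 5 sequences among the lowest 8 in both treatments, went from ranks 4 and 8 to 321 and 1088 without those genes, and TUNAR does not hold it. Chance presence of such sequences in the TUNAR transcript stays open. Of other transcripts of similar length 0.128% hold both GAGGGTTA and TGATCATA as TUNAR does, and 0.674% hold as many as TUNAR (4) of those 5. However, 2.21% hold as many (6) of the lowest 10 in DMSO and 5.23% as many (5) of the lowest 10 in 1-AKP. Which fallen genes depend on TUNAR itself stays open, both for those with a 7-base part of these sequences, which 25.2% of all genes hold, and for those without, such as NKX6-1; the seed may account for a part only, and the siRNA sequences were not used here.

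The second pattern is that short genes rose and long genes fell with 1-AKP. GC-dependent recovery of RNA is argued against by a rank correlation with length of -0.181 given GC content. Length-dependent recovery as the whole cause of the called genes is argued against, since 70.4% of the genes called with negative siRNA remained after removal of the trend. Whether it accounts for the higher ribosomal protein genes cannot be told apart from a response to 1-AKP, because their median lay at the 98.69 percentile of lists matched on length and mean expression with negative siRNA and at 99.67 with TUNAR siRNAs, and the bound set before was the 99th. The medians of 0.176 and 0.189 lay above the central range of the matched lists, whose upper limits were 0.166 and 0.171. The matching was incomplete: the genes drawn from had a median length of 943 bases, against 791 for the ribosomal protein genes. Their median log2 CPM was 7.83 against 8.34. Long genes tended to have lower fold changes with 1-AKP, so the matched lists can understate what length alone would give. With the trend removed, the ribosomal protein list still passed with negative and TUNAR siRNAs, at medians of 0.11 in both. The camera adjusted p was 4.49e-09 and 5.38e-08, and 0.00219 and 0.00341 with an estimated correlation. A response of the cells to 1-AKP stays open and may explain the rest.

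The third pattern is that replicate 1 stands apart in all 4 groups. Passage is argued against, because replicates 1 and 2 share passage 74 and yet their chi-square per degree of freedom was at least 2.89 times that of replicates 2 and 3 in each group. Gene length is argued against by a rank correlation of -0.024, and more delta cells, which would dilute all beta-cell transcripts alike, are argued against for the fall of G6PC2, which exceeded that of INS and of the median beta-cell factor by at least 1.8 in each group. For the rise of SST a small share of delta cells stays open. LEPR differed by 0.24 and RBP4 by -0.10. The ratio of their median difference to that of SST was 0.0249, under the bound set before as counting against delta cells. It does not decide, since both genes already stood above SST in replicates 2 and 3 (LEPR at 11.5 and 10.5 CPM, SST at 4.05 and 5.49), where a small share of such cells would not show. The list of markers of other islet cells was higher in replicate 1 (median difference 0.23), but it includes SST, LEPR and RBP4 and is no separate evidence. Beyond passage the labels name no difference between replicate numbers, and the source of the difference stays open.

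Other splits of the samples were counted for each comparison. With 3 libraries against 3, the 10 splits are too few for a share under 0.05: the real and the highest other counts were 2 and 0 for TUNAR siRNAs in DMSO (1 split as large), 1168 and 1 for 1-AKP with negative siRNA (1 split), 0 and 0 for TUNAR siRNAs in 1-AKP (10 splits), and 1201 and 0 for 1-AKP with TUNAR siRNAs (1 split). That count of 0 in 1-AKP fixes its 10 splits, and for the difference of effects the real count of 0 likewise means that 100 of 100 splits gave at least as many (highest other 6), so these splits say nothing about chance. Swapping siRNA labels within replicate numbers gives 4 splits per treatment, again too few, with 488 against 0 in DMSO and 443 against 1 in 1-AKP (1 split each); the other splits part the same pairs with 1 of the 3 turned round. For both treatments averaged, 1 of 32 splits, the real one, gave 1373 genes and the highest other 37, but this count takes pairs with the same number in both treatments as independent. Turning whole replicate numbers leaves 4 splits, too few for a share under 0.05.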
